A study of Drosophila melanogaster with 10 samples.

How the data were processed

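Nascent RNA was prepared from chromatin of ML-DmBG3-c2 cells after mock treatment, Ph RNAi or Sce RNAi, with depletion of uncapped and polyadenylated RNA and Ion Torrent libraries that keep the native end of each transcript, per the labels' protocols. The 10 libraries fall into 3 mock, 3 Ph RNAi and 4 Sce RNAi, grouped by their titles. The labels number the replicates and do not say whether they came from separate cultures, so the authors' p-values may measure technical spread. The submitters' processing notes name SAMtools and bedtools. The aligner, genome build, annotation, statistical test and q-value method are not given in the sources used here.

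The one table holds 7624 genes. Per the file headers, the authors averaged the signal per gene over the replicates of each group, in 3 nascent RNA columns. Another 4 columns of total RNA group means match no sample of the series. No value from them is given here, although earlier runs used them, as stated in the closing sections. Per the file headers, the authors also gave a ratio of each RNAi mean to the mock mean, and a p-value and a q-value per gene, for nascent RNA after Ph and Sce RNAi and for total RNA after Ph, Sce and Pc RNAi. The total RNA ratios come from libraries outside the 10 samples and serve as a comparison beside the nascent values. Each deposited nascent ratio equalled the quotient of the deposited means within 1% plus 0.001. Ratios, p-values and q-values were deposited with 3 decimals, so an entry of 0 stands for a value under 0.0005. The deposited q-values were close to a fixed share of the Benjamini-Hochberg value of the same p, 0.670 for Ph RNAi and 0.817 for Sce RNAi in nascent RNA. Sums of the nascent columns ran from 191793598 to 192278102, so the authors had brought them to a common total. A global rise or fall of transcription cannot be seen after such scaling. Depth per library is unknown, and strand handling in counting is not given in the sources used here.

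The design fixed before the data were examined gave a replicate test for values per library, and for a table of means a log2 ratio with no test, or the authors' p-values where present. The table holds group means together with the authors' p-values, a mixture that the naming rule did not foresee, so both of its branches were applied. No test across libraries was run. A gene was called changed where the authors' q-value was under 0.05. Log2 ratios were log2((RNAi mean + pseudocount)/(mock mean + pseudocount)), with the 10th percentile of the nascent means, 581, as pseudocount, which understates changes of low genes. For total RNA the log2 of the authors' deposited ratio was taken, with no pseudocount and with a ratio listed at 0 read as 0.0005. Genes with a mean over the 3 nascent columns above 581 were kept, 6942 genes, and 682 were left out. Plain folds in the text are quotients of the authors' means without a pseudocount.

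Genes named by rule were the 10 highest and 10 lowest log2 ratios among genes with means above the median measurable gene in both groups (5 and 5 for Ph RNAi against Sce RNAi), the same numbers among genes with q under 0.05 and a mean above the median, and ph-p, ph-d, Sce, Pc, Psc, E(z), en and inv. The rule also took Polycomb targets and Enhancer of split genes with q under 0.05, and up to 4 genes with q under 0.05 from each other list. Ubx, chinmo, bi, Vsx1, oc, tup and Ama were named by the rule for genes with q under 0.05 after Ph RNAi. Their means over the nascent columns lay above the median, although their mock means lay below the mock median. Other genes used as examples were chosen after their values were seen: list members that did not pass, all 9 genes called after Sce RNAi, and the total RNA examples. Pc was at 1.08 and 1.06 times mock in the nascent Ph RNAi and Sce RNAi columns.

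Before the data were examined, 36 gene lists were fixed, covering Polycomb and trithorax groups, Polycomb targets, signalling, transcription and RNA machinery, cell cycle, metabolism, multicopy RNA genes and markers of neural, glial, blood, muscle, fat body and germ line cells. For the 32 lists with 5 or more genes of measurable signal, the median log2 ratio was placed among 10000 random lists matched on mean signal in 10 classes. That mean covers all 3 nascent columns, so a gene with low mock signal can enter a class through its rise. Random lists were drawn gene by gene, so genes of a list that vary together can make its percentile too extreme. Both comparisons share the mock libraries, so a list can move the same way in both without an effect. Benjamini-Hochberg adjustment over each list alone used the authors' p-values, and Fisher's exact test of called genes, chosen after seeing the data, was adjusted over 66 tests in nascent and in total RNA each. The count of called genes with the same direction in both comparisons was set beside simulations of unchanged groups, also added after seeing the data. Gene models of the reference annotation matched 7517 of 7624 symbols (98.6%), 5725 by symbol and 1792 by synonym, and served for lengths, neighbours and overlaps, with no coordinates taken since the authors' build is not named. Work used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

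The steps were tested on simulated data for 6942 genes with noise of 0.418 in log2. For simulated Ph RNAi against mock, the 1.5-fold mark took 50 of 50 genes changed 4-fold in each direction, 40 of 50 raised 2-fold, 39 of 50 lowered 2-fold and 743 of 6742 unchanged genes. For simulated Sce RNAi the numbers were 50 of 50 each way, 41, 39 and 677. Of 100 unchanged lists, 3 and 2 fell outside the middle 95% of random lists. The simulated noise was independent between genes and these lists were drawn at random. That rate therefore follows from the setting and does not extend to lists whose genes vary together. Alternatives were a pseudocount 10 times smaller or larger, no filter, a filter on means above the median in both groups, median centring, equal column sums and quantile normalization, and, chosen after seeing the data, q under 0.1, Benjamini-Hochberg adjustment of the rounded p, and leaving out genes over 4-fold.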

Results

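Nascent RNA was measured in ML-DmBG3-c2 cells, a Drosophila line derived from the larval central nervous system, after RNA interference (RNAi) against Polyhomeotic (Ph) or against Sce, the fly RING1 homolog. Both proteins are subunits of Polycomb repressive complex 1 (PRC1), which keeps developmental genes silent. The series holds 10 libraries of chromatin-associated nascent RNA, with 3 from mock-treated cells, 3 labelled Ph RNAi and 4 labelled Sce RNAi. The values available were the authors' mean signal of each group for 7624 genes and, in the authors' deposited table, the ratio to mock with a p and a q for each gene. The 3 nascent columns summed to 191793598, 192278102 and 192180746 signal units for mock, Ph RNAi and Sce RNAi, so the authors had brought them to a common total. Depth per library, values per library and the spread between replicates were not given, so no error could be put beside a mean, and the authors' q is the one measure of replicate error used here. A gene is said to have risen or fallen where that q was under 0.05.

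The genes targeted by RNAi were examined first, since they check the labels. The nascent signal of ph-p and ph-d, the neighbouring genes that both encode Ph, was 4.87-fold and 5.39-fold higher than mock in the libraries labelled Ph RNAi, with authors' means of 90923 against 18685 for ph-p and 57853 against 10729 for ph-d. Sce was 118-fold higher in the libraries labelled Sce RNAi, with a mean of 293193 against 2475. In the authors' deposited table ph-p passed the threshold with a q of 0.012, while ph-d had a q of 0.053 and Sce a q of 0.377. In the other protein's columns ph-p and ph-d had 0.935 and 0.969 of their mock signal and Sce had 1.80 times its own. In total RNA of the same treatments the ratios were 8.64 for ph-p, 8.09 for ph-d and 27.0 for Sce in the authors' deposited table. Each targeted gene was thus higher, not lower, under its own label, and the groups are therefore called the libraries labelled Ph RNAi and Sce RNAi, with each direction given below resting on those labels.

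The first comparison, set by the series' design, asked which genes changed their nascent transcription when Ph was targeted. In the libraries labelled Ph RNAi the largest rise was that of Ubx, a Hox gene, 215-fold from an authors' mean of 316 to 67888. Ama, an immunoglobulin-family adhesion gene of the Antennapedia complex, rose 147-fold, and chinmo, a BTB zinc finger gene that acts in neuronal timing and downstream of JAK/STAT signalling, rose 123-fold from 653 to 80372. Transcription factor genes that rose also included bi by 98.2-fold, Vsx1 by 78.4-fold, oc by 76.8-fold, tup by 67.0-fold and zfh2 by 48.5-fold. Fewer genes fell, and among those with strong signal were the axon guidance genes NetA, 5.63-fold lower at 115862 against 652147, and NetB, 3.24-fold lower, with the Wnt receptor gene fz 3.22-fold lower. The authors' deposited table held 129 genes that rose and 60 that fell at q under 0.05, 2.48% of the 7624, and 1257 genes at an unadjusted p under 0.05 where chance alone gives 381.2.

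Among other genes, axo rose 42.2-fold and cpo, an RNA-binding protein gene of the nervous system, rose 27.1-fold. The cell adhesion gene Nrg rose 6.73-fold, the sodium pump subunit gene nrv2 rose 4.64-fold, the lactate dehydrogenase gene ImpL3 rose 4.44-fold and the ecdysone-inducible gene Eip75B rose 3.12-fold. Smaller rises were those of nmo, a kinase gene, by 2.23-fold and key, an immune signalling gene, by 2.13-fold. The falls also included Fili by 5.05-fold, CG18788 by 5.32-fold, CG8468 by 3.91-fold, CG13358 by 3.58-fold, shf by 3.46-fold, GABA-B-R3 by 3.38-fold and CG4829 by 3.37-fold. Ppn, which encodes an extracellular matrix protein, fell 3.20-fold, the cadherin gene CadN fell 2.08-fold, the trithorax group gene tna fell 1.71-fold and the ecdysone-response gene Eip74EF fell 1.59-fold. All genes named in this paragraph had q under 0.05 in the authors' deposited table. The gene model of bi is overlapped over 100% of its length by an antisense RNA gene and that of Antp over 60.3% by CG46458, so the origin of their signal is uncertain. The mock means of Ubx, bi, Vsx1, oc, tup and Ama lay below the pseudocount of 581, so the size of their folds is uncertain, and on the log2 scale with that pseudocount Ubx rose by 6.25.

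A list of classical Polycomb targets, fixed before the data were examined, held 80 genes, of which 35 were in the table. In the libraries labelled Ph RNAi 10 of these 35 rose and 0 fell at q under 0.05 in the authors' deposited table. The 10 were Ubx, oc, tup, Antp at 32.1-fold, mirr at 18.3-fold, Dll at 17.8-fold, dac at 15.8-fold, salr at 15.7-fold, salm at 10.5-fold and NK7.1 at 5.21-fold. Adjusted over the list alone, 21 were higher and 5 lower at a Benjamini-Hochberg value under 0.05 computed from the p of the authors' deposited table. The list's median log2 ratio over its 29 genes with measurable signal was 2.37, above all 10000 random lists matched on mean signal. Members with low mock signal could pass the filter and reach their class through the Ph RNAi column. For oc the authors' mean was 246 in mock and 18886 after Ph RNAi. That placement is thus partly built in and is not read as a test. The list's 10 rises were more than its size gives by Fisher's exact test, one-sided (p = 1.7e-10, adjusted p = 1.1e-08 over 66 tests of lists and directions), and no other list passed. Scr, Abd-B, Poxm and Optix, also on the list, had nascent signal 53.5, 55.4, 61.7 and 68.7 times mock without passing, with q of 0.08, 0.089, 0.173 and 0.15 in the authors' deposited table. The mock means of Dll, dac, salr, salm, Scr, Abd-B and Optix also lay below the pseudocount, so the size of their folds is uncertain, and with the pseudocount salr and salm rose by 2.25 and 1.80 in log2.

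The members of this list that mock cells already transcribed strongly, singled out after their values were seen, gave other values. C15, a homeobox gene with an authors' mock mean of 211396, was 9.21-fold lower in the libraries labelled Ph RNAi, Lim1 with 592137 was 2.77-fold lower, hth with 867613 was 1.99-fold lower and pnr with 136748 was 1.52-fold lower. Their q values in the authors' deposited table were 0.056, 0.096, 0.057 and 0.076, so none of the 4 passed. The neighbouring genes bab2, with a mock mean of 246195, and bab1, with 10807, had ratios of 0.823 and 0.765 with q of 0.46 and 0.444 in the authors' deposited table. Of the engrailed pair, en was 2.05-fold lower from a mean of 1961 (q 0.106) and inv was 1.16-fold lower from 91402 (q 0.596) in the authors' deposited table. When only list members with means above the median measurable gene in both groups were kept (5406 in mock and 5620 in Ph RNAi), 8 remained and their median log2 ratio was -0.48 after Ph RNAi and -0.54 after Sce RNAi. NK7.1 was the 1 gene among these 8 with a ratio above 1 after Ph RNAi. By construction this filter removed members with lower signal in mock cells, among them mirr, which rose 18.3-fold from an authors' mean of 4970, close under the mark.

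Other lists stood apart from random lists by their median log2 ratio in the libraries labelled Ph RNAi, although few of their genes passed. Percentiles among random lists take no account of replicate error or of genes that vary together within a list. For JAK/STAT and neural stem cell genes they also favour members raised from low mock signal, since the matching mean includes the Ph RNAi column. The glycolytic enzymes had a median of 1.00, at percentile 100, with 9 of 12 genes higher at an unadjusted p under 0.05 and 1 of them (ImpL3) at q under 0.05 in the authors' deposited table, and 9 when adjusted over the list alone. Pgi, Ald and Pglym78 of this list were 2.16, 2.23 and 2.51 times mock. JAK/STAT genes had a median of 1.04 (0.033 over the 5 with means above the median gene in both groups, inside random lists) with chinmo the 1 that rose, while the cytokine genes upd2 and upd3 were 33.4 and 17.0 times mock with q of 0.17 and 0.104 in the authors' deposited table. Heat shock genes had a median of 1.05 with 0 of 20 at an unadjusted p under 0.05 in the authors' deposited table, and near-identical Hsp70 copies among them share reads. Genes of neural stem cells had a median of 1.85 over 6 genes, of which nub rose 11.5-fold, or by 2.26 in log2 with the pseudocount. The mock means of nub, upd2 and upd3 lay below the pseudocount, so the size of their folds is uncertain. Lists with low medians were DNA replication at -0.47, where 10 of 31 genes were lower at an unadjusted p under 0.05 and 0 at q under 0.05 in the authors' deposited table, and mitosis at -0.44, where the counts were 9 of 28 and 0. Adjusted over the list alone, 0 replication genes and 2 mitosis genes were lower. In these lists Mcm2, Mcm7 and BubR1 were 2.07, 2.23 and 2.37 times lower than mock, and an antisense RNA gene covers 81.2% of the model of Mcm7, so its signal is uncertain in origin.

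Markers of other cell types were followed because a cultured line can hold or resemble them. Blood cell genes had a median log2 ratio of -0.58 at percentile 0.09 in the libraries labelled Ph RNAi, with Ppn the 1 of 11 that fell and, adjusted over the list alone, 5 lower and 1 higher. The type IV collagen genes vkg and Cg25C, whose mock means of 1415310 and 2029895 were among the highest in the table, were 2.68-fold and 2.60-fold lower with q of 0.058 and 0.06 in the authors' deposited table. Neuronal markers had a median of 0.33 with Nrg higher and CadN lower, glial markers had -0.20 with nrv2 higher, and muscle markers had -0.08 with 0 of 7 at an unadjusted p under 0.05 in the authors' deposited table. Fat body and germ line markers, with 4 genes, had a median of -0.67. After Sce RNAi the same 5 lists had medians of 0.15, 0.17, -0.36, 0.00 and -0.32 in the order given.

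**Figure D1:**
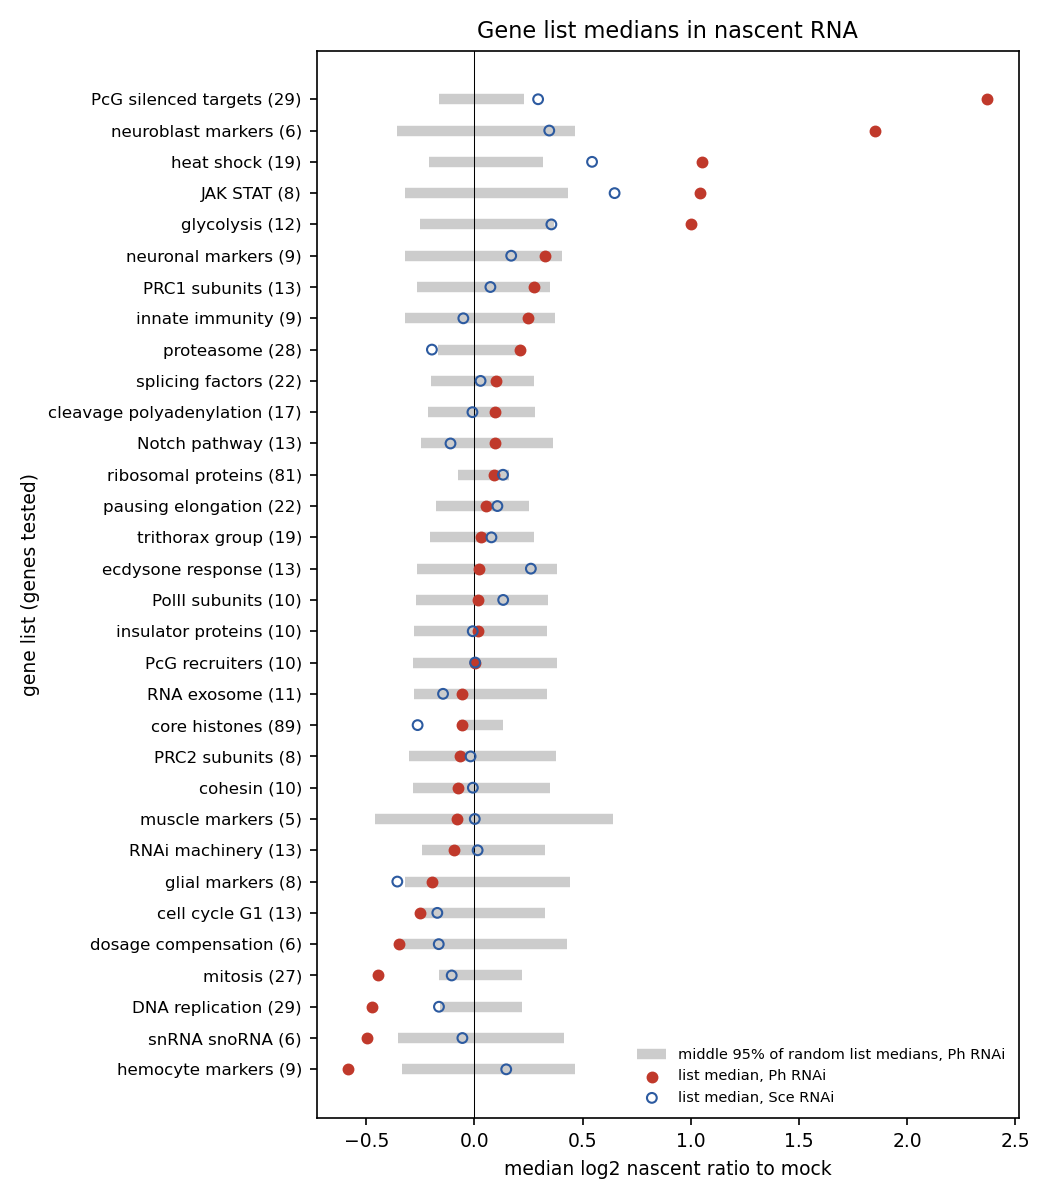
Median log2 nascent ratio to mock of each gene list with 5 or more genes of measurable signal (horizontal axis), with filled points for Ph RNAi, open points for Sce RNAi, and grey bars for the middle 95% of the medians of 10000 random lists matched on mean signal (Ph RNAi). Polycomb targets lie farthest to the right at 2.37 and blood cell genes farthest to the left at -0.58.

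For the other lists the medians of the log2 ratio after Ph RNAi were 0.27 for PRC1 subunits, -0.07 for PRC2 subunits, 0.00 for Polycomb recruiters, 0.03 for trithorax group genes, 0.09 for the Notch pathway, -0.08 for cohesin and 0.02 for insulator proteins. Genes of the transcription and RNA machinery had medians of 0.05 for pausing and elongation factors, 0.02 for RNA polymerase II subunits, 0.10 for cleavage and polyadenylation, 0.10 for splicing factors, -0.06 for the RNA exosome and -0.09 for the RNAi machinery. Ribosomal protein genes had a median of 0.09, core histone genes -0.06, proteasome genes 0.21, innate immunity genes 0.25 and ecdysone-response genes 0.02. The core histone list also holds copies of the linker histone gene His1. Of the lists in this paragraph 3 lay outside the middle 95% of random lists, with 0 genes at q under 0.05 in the authors' deposited table. The 3 were the list written for small nuclear and nucleolar RNA genes at -0.50 (percentile 0.52), dosage compensation genes at -0.35 (percentile 2.30) and G1 and S phase regulators at -0.25 (percentile 2.21). All 7 genes of the first of these lists were Uhg genes, hosts of small nucleolar RNAs. Its median therefore does not describe small nuclear or nucleolar RNA genes themselves. The dosage compensation median no longer stood outside at -0.19 with a pseudocount 10 times larger or at -0.21 without a filter, nor did the G1 and S phase median at -0.23 with means above the median in both groups or at -0.33 with quantile normalization. The 3 genes of the Enhancer of split complex with measurable signal had a median of 0.28, and lists of the mitochondrial genome and of transfer and ribosomal RNA genes had 0 genes in the table. The PRC1 genes Psc and Su(z)2 were 2.18 and 2.22 times mock with q of 0.1 and 0.053 in the authors' deposited table, and E(z) of PRC2 was at 0.82 times mock.

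By size alone, 838 of 6942 genes with measurable signal were over 1.5-fold higher and 578 over 1.5-fold lower in the libraries labelled Ph RNAi. Genes with strong signal and large ratios that did not pass were rho at 24.8 times mock, CG42741 at 21.9, CG43462 at 13.7, Ets21C, an ETS factor gene, at 12.6, MESK2 at 12.3 and vari at 11.3, with q from 0.054 to 0.159 in the authors' deposited table. The photoreceptor kinase gene sev, 10.2-fold higher, did pass with a q of 0.017 in the authors' deposited table, and Sulf1, Lmpt and CG42673 were 8.92, 8.88 and 8.56 times mock without passing. At the other end CG15828 was 11.8-fold lower, LpR1 6.24-fold, Rgk1 5.24-fold, CG7991 5.06-fold, Adgf-A 4.59-fold, Alk, a receptor kinase gene, 4.23-fold and beat-IIIc 4.00-fold, none of them with q under 0.05 in the authors' deposited table. The models of CG42741 and rho lie wholly within twi and Ptp61F on the opposite strand, and that of Adgf-A is shared by 74.2% with Adgf-A2, so these signals are uncertain in origin. In 2 simulations of unchanged genes with the spread of the Sce RNAi ratios taken wholly as noise, 743 and 677 of 6742 genes passed the same 1.5-fold mark. These counts follow from that choice of noise. The noise between replicates was not available, so the share of unchanged genes that pass is not known and size alone is not read as a change. Quantile normalization of the group means gave 672 higher and 766 lower, a share of 46.7% higher in place of 59.2%.

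The second comparison asked the same of Sce. In the libraries labelled Sce RNAi few genes changed, and those that did were a mixed group, named here after their values were seen. The zinc finger homeobox gene zfh2 rose 11.3-fold from an authors' mean of 2477 to 28066, klu, a zinc finger gene, rose 6.47-fold, the lamin gene LamC rose 5.38-fold, cpo rose 4.97-fold and Nhe2, a sodium/hydrogen exchanger gene, rose 1.68-fold. The falls were those of the esterase gene alpha-Est1 by 4.52-fold, CG42390 by 2.48-fold, wun, a lipid phosphatase gene, by 2.30-fold and gukh by 2.09-fold. These 9 genes, 5 higher and 4 lower, were all that had q under 0.05 in the authors' deposited table, where 755 genes had an unadjusted p under 0.05 against 381.2 by chance. The mock means of LamC and CG42390 lay below the pseudocount, with which their log2 ratios were 1.64 and -0.42, so the size of their folds is uncertain. Other gene models cover 100% of LamC and 95.5% of Nhe2, so their signal is uncertain in origin. All 9 rest on p values listed at 0, and Benjamini-Hochberg adjustment of the rounded p gave 23 genes if that entry is read as 0 and 0 genes if it is read as 0.0005.

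In the libraries labelled Sce RNAi the median log2 ratio of Polycomb targets was 0.29 at percentile 99.94, and 0 of 35 had q under 0.05 in the authors' deposited table, with 8 higher and 3 lower when adjusted over the list alone. With a pseudocount 10 times larger the median was 0.054 at percentile 90.85, no longer outside random lists. Values without a call included mirr at 15.2 times mock (authors' mean 75562 against 4970), Abd-B at 19.5, Antp at 7.36, Ubx at 4.13 and NK7.1 at 3.20, those of Abd-B and Ubx being of uncertain size as their mock means lay below the pseudocount. The integrin gene if was at 5.90 times mock, Myo31DF at 3.24 and Su(z)2 at 3.13, with q of 0.093, 0.137 and 0.119 in the authors' deposited table, and Psc at 2.44. Ets21C, CG43462, mamo, Sulf1, Gld2 and Lmpt were 6.51, 4.57, 3.83, 3.58, 2.87 and 2.79 times mock, that of Gld2 being uncertain in origin since its model lies wholly within SKIP on the same strand. CG15828 was 7.40-fold lower, Alk 4.14-fold, shf 3.86-fold, C15 3.67-fold, Fili 3.44-fold, CG34380 3.38-fold, shd 3.31-fold, the Notch modifier gene fng 3.02-fold, ome 3.00-fold and Adgf-A 2.79-fold, none with q under 0.05 in the authors' deposited table. Over 1.5-fold, 479 genes were higher and 348 lower.

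Among the other lists after Sce RNAi, JAK/STAT genes had a median log2 ratio of 0.65, heat shock genes 0.54 and glycolytic enzymes 0.36, each above the 99th percentile of random lists at 99.99, 100 and 99.53. At an unadjusted p under 0.05 were 0 of 20 heat shock and 0 of 12 glycolysis genes in the authors' deposited table. Of 8 JAK/STAT genes 2 were higher and 1 lower there. Both comparisons share the mock libraries, so a list that moved the same way after Ph RNAi is not separate evidence. Core histone genes had -0.26 at percentile 0, proteasome genes -0.20 at 0.61, glial markers -0.36 at 0.19 and DNA replication genes -0.16 at 1.42. With means above the median in both groups the JAK/STAT median was -0.079 (percentile 23.95) and the glial median 0.13 (percentile 65.35), both of the opposite sign, and the proteasome median was -0.11 (percentile 8), all inside random lists. With a pseudocount 10 times larger the glial median was -0.13 (percentile 2.70), also inside. Mitosis genes had -0.11 at percentile 7.09 and neural stem cell genes 0.35 at 96.74. No gene of these lists had q under 0.05 in the authors' deposited table in the libraries labelled Sce RNAi. Histone genes are near-identical copies whose reads cannot be assigned to 1 gene. Random lists of separate genes are therefore too narrow a measure for the histone list, and its percentile of 0 is not read as a result.

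Ph and Sce belong to the same complex, so the changes were set side by side. Of the 129 genes that rose after Ph RNAi, 102 had a ratio above 1 after Sce RNAi, and of the 60 that fell, 54 had a ratio below 1, in the authors' deposited table. In 100 simulations of unchanged groups that share the mock libraries, 113 of the 129 genes ranked highest (106 to 122) and 52.8 of the 60 ranked lowest (45 to 59) had the same direction. The count of 102 lay below that range and the count of 54 inside it. These simulations rank noise alone, unlike genes called with the ratios seen here, so they show only that a high count can arise without an effect. The median ratio of the 129 was 4.09 after Ph RNAi and 1.42 after Sce RNAi, and that of the 60 was 0.442 and 0.729, in the authors' deposited table. Genes with q under 0.05 in both comparisons of the authors' deposited table and in the same direction were 3 higher (zfh2, cpo and Nhe2) and 2 lower (alpha-Est1 and wun). The gene gukh passed in both with opposite directions, rising 1.66-fold after Ph RNAi and falling 2.09-fold after Sce RNAi.

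**Figure D2:**
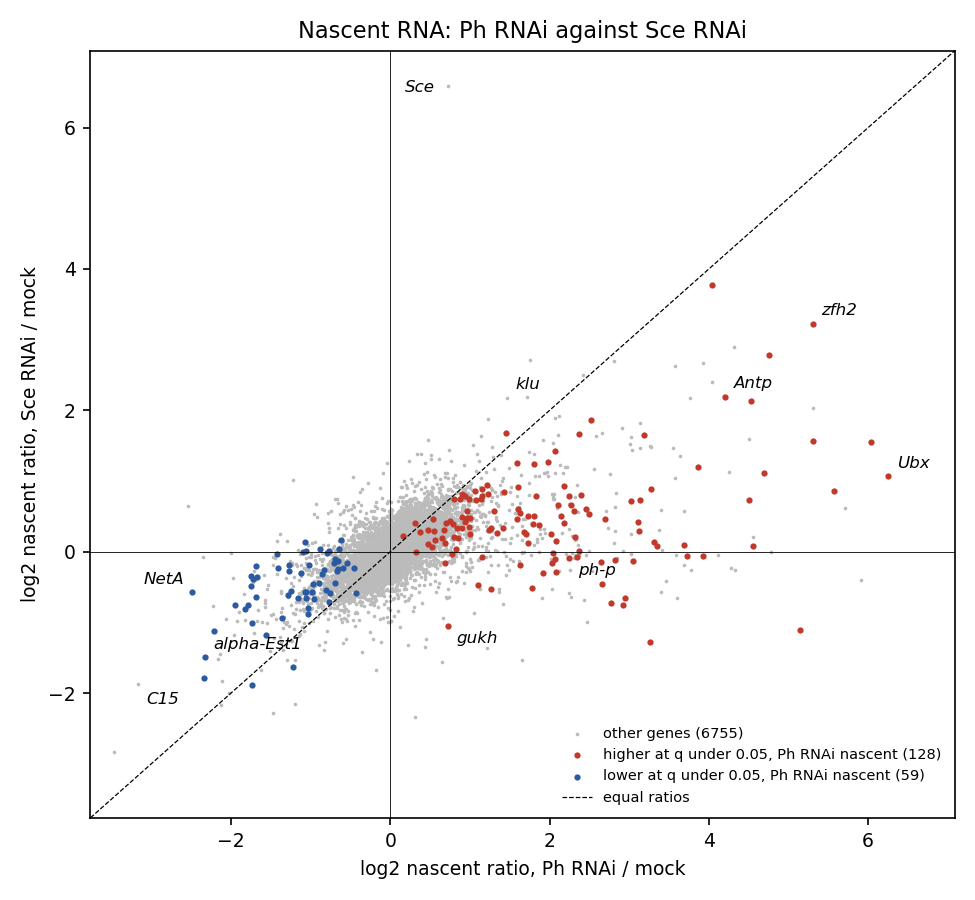
Log2 nascent ratio to mock with the pseudocount for 6942 genes after Ph RNAi (horizontal axis) and after Sce RNAi (vertical axis), in red the 128 and in blue the 59 plotted genes that rose or fell after Ph RNAi at q under 0.05 in the authors' deposited table, with equal ratios on the dashed line. Most red points lie to the right of the line and Sce stands alone at the top.

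Across 6942 genes the log2 ratios of the comparisons had a Pearson correlation of 0.584 and a Spearman correlation of 0.652, genes not being independent replicates. Both comparisons share the 3 mock libraries, and 100 simulations in which the whole spread of the Sce RNAi ratios was noise shared through mock gave a correlation of 0.533. The simulated Ph RNAi ratios also took their noise from the Sce RNAi ratios, while the observed variances were 0.464 after Ph RNAi and 0.183 after Sce RNAi. The simulated spread after Ph RNAi was thus too small. This raises the simulated correlation and the simulated share of genes with the same direction, so neither can be set directly against the observed value. The covariance was 0.170 against 0.104 in those simulations, and 75.1% of genes had the same direction against 67.9%. Without the 173 genes over 4-fold in either comparison the covariance was 0.116 against a simulated 0.081, so part of the excess came from those genes. At an unadjusted p under 0.05 196 genes were higher in both comparisons of the authors' deposited table, where independent lists give 34.6 and the simulations gave 140 on average and 164 at most. For genes lower in both the numbers were 177 in the authors' deposited table, 26.9 for independent lists, and 119 on average and 137 at most in the simulations. The mock libraries could not be split, so part of the excess over independent lists may come from the shared controls.

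The direct comparison of Ph RNAi with Sce RNAi columns was made by size alone, since the authors' columns hold no test of that difference. Among genes with means above the median measurable gene in both columns (5620 and 5430), the largest log2 differences toward Ph RNAi were those of rho at 4.35, the muscle protein gene zormin at 3.68, MESK2 at 3.63, the arginine kinase gene Argk at 3.50 and CG31690 at 3.46, while CG42741, with an authors' mean of 5130 after Sce RNAi just under that limit, had 4.59. Toward Sce RNAi they were LpR1 at -3.19, Rgk1 at -2.28, beat-IIIc at -1.98, NetA at -1.92 and the collagen gene Cg25C at -1.63. Over 1.5-fold, 494 genes were higher in Ph RNAi and 304 higher in Sce RNAi. Among the 129 genes that rose after Ph RNAi the ratio was farther from 1 after Ph RNAi than after Sce RNAi for 125, and among the 60 that fell for 57, genes picked by their Ph RNAi values in the authors' deposited table.

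The series' title concerns active genes, so changes were counted by the level of transcription in mock cells. Genes above the median mock mean of 4447, such as Fili, NetA, Nrg and nmo, made up 72 of the 129 that rose and 50 of the 60 that fell after Ph RNAi in the authors' deposited table. Genes at or below that median, such as Ubx, chinmo and Antp, made up 57 of the rises and 10 of the falls in the authors' deposited table. The median ratio of the rises was 2.29 above and 13.04 at or below the median in the authors' deposited table. The mock mean is also the denominator of the ratio. A split on it therefore favours larger rises and fewer falls among genes at or below the median. These counts and medians cannot show whether the response depended on the level of transcription. Among the 10% of genes with the strongest mean nascent signal, 19.5% were over 1.5-fold higher and 12.4% over 1.5-fold lower after Ph RNAi, and 34 rose and 20 fell in the authors' deposited table. In the weakest 10% of measurable genes the shares were 10.6% and 7.48%, and 7 genes rose and 2 fell in the authors' deposited table. The share over 1.5-fold among the weakest 10% depends on the pseudocount, being 18.1% in either direction as computed and 37.99% with a pseudocount 10 times smaller. Long genes passed 1.5-fold more often in both directions, with 25.7% of the longest 10% of genes higher and 13.7% lower against 9.20% and 4.82% of the shortest. Signal and gene length were not separated here, so the patterns by signal and by length may be the same one. Counts at q under 0.05 may also reflect how well a gene was measured, since the spread between replicates is not known.

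The authors' deposited table also holds ratios to mock with p and q for total RNA of the same treatments, from libraries outside the 10 analysed here, and these were set beside the nascent values. After Ph RNAi the total RNA of Abd-B, Scr and Poxm, not called in nascent RNA, rose with ratios of 2083, 2710 and 38.1 and q of 0.007, 0.005 and 0.007 in the authors' deposited table. Ratios of this size carry no pseudocount, so their size is uncertain. Of the 129 genes that rose in nascent RNA, 123 had a total RNA ratio above 1 and 58 also rose in total RNA, where independent lists give 4.53, in the authors' deposited table. NetA, Fili and GABA-B-R3 were among the 5 of 60 that fell in both, where independent lists give 0.22, and 53 of the 60 had a total RNA ratio below 1, in the authors' deposited table. The Polycomb target list had 20 of 35 members higher and 1 lower (C15) in total RNA at q under 0.05 in the authors' deposited table, where 268 of all 7624 genes rose (Fisher's exact test, one-sided, p = 8.3e-21, adjusted p = 5.5e-19 over 66 tests). Of the 7 genes of the Enhancer of split complex, a locus of Notch-responsive genes that also holds the corepressor gene gro, 5 rose in total RNA (p = 1.0e-06, adjusted p = 3.4e-05 by the same exact test), with HLHm3 at a ratio of 19.9, m6 at 35.9, malpha at 20.7, HLHmbeta at 7.65 and gro at 1.42 in the authors' deposited table. The other members, m2 and HLHm7, had ratios of 5.52 and 5.35 with q of 0.078 and 0.079, and 0 of 7 had q under 0.05 in nascent RNA, in the authors' deposited table. Only 3 of the 7 had measurable nascent signal, all 3 with log2 ratios above 0 after Ph RNAi. The nascent ratio of HLHmbeta was 2.03 with a q of 0.059 in the authors' deposited table. An absence of nascent change at this locus is therefore not shown. Neural stem cell genes also passed with 3 of 6 higher (adjusted p = 0.017 by the same exact test) and no other list did. Across genes the nascent and total log2 ratios had a Pearson correlation of 0.609 and a Spearman correlation of 0.363 after Ph RNAi, and 0.353 and 0.290 after Sce RNAi, genes not being independent replicates.

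**Figure D3:**
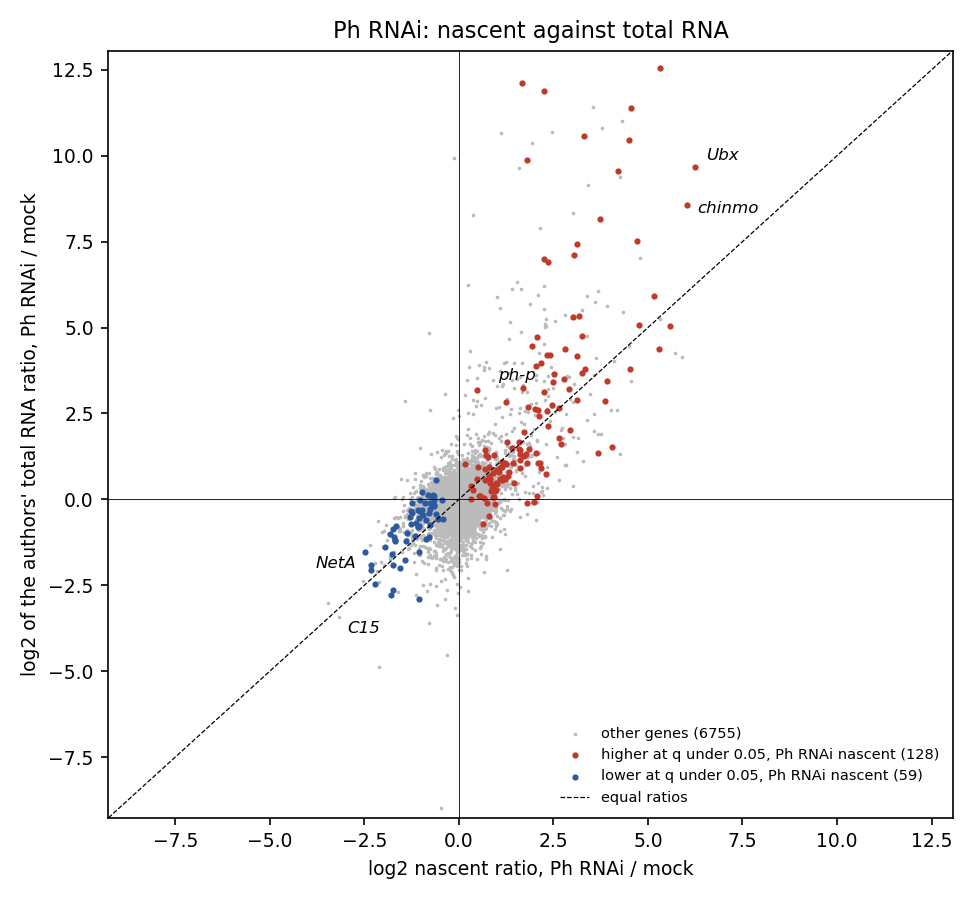
Log2 ratio of Ph RNAi to mock for 6942 genes in nascent RNA with the pseudocount (horizontal axis) and log2 of the total RNA ratio in the authors' deposited table without one (vertical axis), in red the 128 and in blue the 59 plotted genes that rose or fell in nascent RNA at q under 0.05 in the authors' deposited table, with equal ratios on the dashed line. Of all 129 that rose in nascent RNA, 123 had a total RNA ratio above 1.

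After Sce RNAi the total RNA of 18 genes rose and that of 1 fell at q under 0.05, and 0 of these were among the 5 and 4 called in nascent RNA, in the authors' deposited table. They included the PRC1 genes Su(z)2 and Psc, with ratios of 5.81 and 2.78, NK7.1 with 2.22 and aPKC, a polarity kinase gene, with 1.60, the last named after its value was seen, in the authors' deposited table. After Ph RNAi the ratios of Psc and Su(z)2 in total RNA were 3.24 and 5.24, with q of 0.029 and 0.062, in the authors' deposited table. Adgf-A was the 1 gene that fell, with a ratio of 0.385 in the authors' deposited table.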

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

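All tests of the targeted genes and the scaling test of the replication, mitosis and glycolysis lists were chosen after the result was seen, and the gene length test was set before. The transcript length comparison in total RNA was also set before and was recomputed on the authors' ratios after a first result on total RNA group means had been seen. A comparison with genes of matched total RNA level, also set before, was run on those means and is not reported here, because the means match no sample of the series.

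Total RNA after Pc RNAi, outside the nascent comparisons, gave 243 genes at q under 0.05 in the authors' deposited table, 232 higher and 11 lower, a signal in columns that no nascent library matches. Scr, Abd-B and Antp rose with ratios of 21271, 1914 and 604, of uncertain size, and C15 fell with a ratio of 0.115, in the authors' deposited table. Of the 232 that rose, 82 also rose in total RNA after Ph RNAi where independent lists give 8.16, and 14 of the 18 that rose after Sce RNAi were among them where independent lists give 0.548, in the authors' deposited table. These comparisons share 1 mock group, which raises such overlaps without any effect and which the values for independent lists leave out. A value for shared controls was not simulated, since the number of total RNA libraries is not given in the sources used here.

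The targeted genes were higher than mock under their own label in nascent and total RNA. Loss of PRC1 repression at these genes is argued against as the whole cause by their median ratio of 1.06 in the other proteins' RNAi columns, in the authors' deposited table. Sce RNAi columns weigh little here, as 0 of 35 Polycomb targets had q under 0.05 there in nascent RNA. In total RNA after Pc RNAi, where 232 genes rose, ph-p and ph-d had ratios of 1.29 and 1.27. After Ph RNAi Sce had 1.80 in nascent and 1.45 in total RNA, so a smaller part stays open for Sce. An exchange of the Ph RNAi and Sce RNAi columns is argued against by a lowest ratio of 0.877 for ph-p, ph-d and Sce in the other protein's columns of the authors' deposited table, since the targeted genes were not depleted under the other label. Sequenced double-stranded RNA or its products may account for the rise, as all 7 own ratios were at least 4.87 while the highest of 13 others was 1.80, in the authors' deposited table. Values along each gene, which would show whether the signal is limited to the RNAi fragment, were not analysed here.

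Ribosomal protein and histone genes had low total RNA ratios after Ph RNAi, with median log2 of -0.82 over 80 genes and -1.19 over 89 genes of the authors' deposited table against nascent medians of 0.09 and -0.06. Other genes of matched transcript length had total RNA medians of -0.27 (middle 95% of random sets -0.39 to -0.16) and -0.50 (-0.57 to -0.42), a share of 0.332 and 0.418 of each list's median. A bias against short transcripts is therefore argued against as the whole cause, by the bound set before, and stays open as a part of it. For histone genes the margin was small, the bound had been written for ribosomal protein genes, and the first run on group means had left it undecided. Over all 82 ribosomal protein and 100 histone genes, total RNA medians were -0.82 and -1.04 after Ph RNAi in the authors' deposited table. They were -0.41 and -0.50 after Sce RNAi and -0.46 and -0.22 after Pc RNAi, so low ratios were not limited to Ph RNAi. These comparisons share 1 mock group. No biological explanation was tested.

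DNA replication and mitosis genes had low and glycolysis genes high nascent medians after Ph RNAi. Gene length is argued against, since length-matched genes had medians of at most 0.0174 of a list's own in the same direction. A scaling of the columns that varies with signal is argued against as the whole cause, since after quantile normalization, which moved other counts, the medians were -0.55, -0.54 and 0.88 and still outside random lists. In total RNA after Ph RNAi the same lists had median log2 ratios of 0.08, 0.05 and 0.31 with 0 genes lower at an unadjusted p under 0.05 in the authors' deposited table, and no biological explanation was tested. In nascent RNA 0 replication or mitosis genes and 1 glycolysis gene had q under 0.05 in the authors' deposited table.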

How the results depend on the processing

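The alternatives on q and on p rounding and the removal of genes over 4-fold were chosen after seeing the data. No paired analysis was possible because the table holds group means with no replicate columns, and for the same reason the edgeR, DESeq2 and limma alternatives, fits of fewer libraries, leaving out replicates, the fold threshold test and the removal of multicopy RNA before scaling were not run. Median centring and equal column sums moved no count by over 1.5 times and ended no list result. Across alternatives the correlation of Ph RNAi and Sce RNAi ratios ranged from 0.577 to 0.632, and the log2 ratios of Sce, ph-d and ph-p under their own labels from 5.17 to 6.85, 1.94 to 2.42 and 1.98 to 2.28. Of 517 single gene values, 81 no longer passed 1.5-fold with the larger pseudocount and 21 newly did with the smaller one. No value over 1.5-fold changed sign, but by construction a pseudocount or a filter cannot change a sign, so only centring or rescaling of the columns tested this.

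With a pseudocount 10 times smaller, 531 genes were over 1.5-fold lower after Sce RNAi (348 as reported), the weakest 10% of genes had 37.99% (18.1%) and 31.8% (10.4%) over 1.5-fold after Ph and Sce RNAi, and neural stem cell genes after Sce RNAi stood outside random lists at 0.49. With one 10 times larger, the counts higher and lower were 409 and 211 after Ph RNAi, 158 and 82 after Sce RNAi and 257 and 112 between them (838 and 578, 479 and 348, 494 and 304 as reported), and the weakest 10% of genes had 0% in both. By construction a pseudocount moves low genes most. Core histones (-0.028), whose copies are not independent genes, and proteasome genes (0.14) after Ph RNAi then stood outside random lists. Dosage compensation genes (-0.19) after Ph RNAi and Polycomb targets (0.054) and glial markers (-0.13) after Sce RNAi no longer did. Without a filter, the weakest 10% of genes had 6.03% after Sce RNAi, dosage compensation genes after Ph RNAi (-0.21) no longer stood outside and ecdysone-response genes after Sce RNAi (0.26) did.

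With means above the median in both groups, fewer genes were tested, which by construction lowered the counts to 380 and 261, 198 and 126, and 208 and 129, and the weakest 10% of genes to 2.22% and 1.90%. Polycomb targets reversed to -0.48 and -0.54 because members with lower mock signal were removed, and after Sce RNAi JAK/STAT genes (-0.079) and glial markers (0.13) reversed. JAK/STAT genes (0.033) and G1 regulators (-0.23) after Ph RNAi and proteasome genes (-0.11) after Sce RNAi no longer stood outside random lists, and innate immunity genes (0.60) after Ph RNAi did. With quantile normalization G1 regulators after Ph RNAi (-0.33) no longer stood outside and ecdysone-response genes after Sce RNAi (0.28) did. For list changes other than that of the Polycomb targets the cause was not tested. At q under 0.1, 534 and 20 genes passed after Ph and Sce RNAi in the authors' deposited table, and Benjamini-Hochberg adjustment gave 163 after Ph RNAi with p listed at 0 read as 0 or as 0.0005, and 23 or 0 after Sce RNAi. Depth is unknown, so its limit could not be given.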

Other observations

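The tests of neighbouring genes were set before their result was seen, while the genes in the first paragraph were chosen after their values were seen.

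Several genes had nascent ratios on opposite sides of mock after the 2 RNAi treatments. The photoreceptor kinase gene sev, the muscle protein gene zormin, axo and Argk rose 10.2-fold, 7.82-fold, 42.2-fold and 6.92-fold after Ph RNAi and were at 0.374, 0.576, 0.358 and 0.597 of mock after Sce RNAi, the difference not being tested. None of these 4 passed after Sce RNAi, with q of 0.31, 0.295, 0.27 and 0.423 in the authors' deposited table. Their total RNA ratios after Sce RNAi were 1.591, 0.858, 3.019 and 1.285 there, so a fall after Sce RNAi is not shown. CG42390 was 24.9 times mock after Ph RNAi with a q of 0.059 in the authors' deposited table and fell 2.48-fold after Sce RNAi, from an authors' mean of 419 that lies below the pseudocount. The lipid phosphatase gene wun fell in both nascent comparisons, and its total RNA was at 0.251, 0.464 and 0.262 of mock after Ph, Sce and Pc RNAi with q of 0.135, 0.292 and 0.289 in the authors' deposited table.

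Genes that rose after Ph RNAi might change together with their neighbours, as a hypothesis from the spread of Polycomb domains. Adjacent genes were those consecutive on a chromosome among genes with measurable signal and a gene model, with no limit on distance. Genes absent from that set may lie between them. Among 126 genes that rose and had a gene model, 8 adjacent pairs both rose, against a mean of 2.29 and a highest value of 8 in 1000 permutations within 10 classes of mean signal. Without pairs whose own models overlap and may share signal, 6 pairs remained where the permutations gave a median of 2, a 95th percentile of 5 and a highest value of 7. Of these 6, Adh and mol may still reflect shared signal, since the model of Adh overlaps that of osp, which also rose. Without Adh and mol the count would not lie above the 95th percentile, so the test cannot decide whether overlapping models are the whole cause. The pairs without overlap were salr and salm, CG5001 and CG5397, Lip4 and Trim9, Adh and mol, key and Reg-5, and CG16718 and Vha13. The pairs with overlapping models were osp and Adh, and NK7.1 and CG31320.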
